A study of Mus musculus and Homo sapiens with 40 samples.

How the data were processed

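The series held 40 samples: 28 mouse RNA-seq libraries and 12 small RNA libraries, of which 6 small RNA libraries came from human cell lines. RNA was isolated with TRIzol, and libraries were made with TruSeq stranded mRNA or NEBNext small RNA kits, per the labels' protocols. Reads were trimmed with Trimmomatic 0.39 and aligned with HISAT2 (RNA-seq) or Bowtie, build mm9, per the submitters' processing notes. The notes name mm9 for the human libraries too, so the human reference, like the counting program and the annotation, is not given in the sources used here.

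All 7 deposited tables were treated as normalised signal as deposited by the authors. Of the values in every table, 100% were whole multiples of 1 step per library within a tolerance of 0.01, so whole reads could be recovered. RNA-seq values equalled reads times 10000000 divided by a whole number larger than the reads assigned to genes. What that denominator counts is not given in the sources used here. Among the mESC miRNA libraries and among the human ones, 1 library summed to exactly 1000000 (the 2nd WT library and HCT116), and every other library carried its own factor relative to it. The origin of those factors is not given in the sources used here. The neural miRNA values had whole denominators of 6085349 (day 0) and 1851551 (day 5).

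Reads assigned per library ran from 11426357 to 32882480 in RNA-seq and from 302858 to 4731304 in small RNA. The mouse RNA-seq tables listed 20593 (mESC), 25200 (EpiLC), 25174 (embryoid bodies and neural) and 14059 (GW9662) named genes. Entries named by a number, 26, 0, 24 and 20 in the same order, were left out because a gene symbol converted by a spreadsheet cannot be restored. The miRNA tables listed 844 (mESC), 1384 (neural) and 1464 (human) miRNAs. Replicate libraries differed by more than sampling noise, with a chi-squared per degree of freedom from 4.38 to 34.2.

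The design written before the data were examined asked for edgeR on counts and for limma otherwise. Because the values were signal, limma with a mean-variance trend was run on log2(value + 1). Genes entered with a mean value of at least 1 and miRNAs with a mean of at least 10 over the libraries of a fit. Calls used a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The 6 serum/LIF mESC libraries shared 1 fit, as did the 8 EpiLC libraries. Embryoid bodies had 1 library per genotype and day, so day entered as a factor beside genotype. Comparisons of 1 library against 1 were described by fold changes among genes with a value of at least 50 in 1 library, without a test. All fold changes were computed with a pseudocount of 1. Scaling to the median ratio of features with a mean of at least 10 was set down for the tested comparisons and for GW9662 before the data were examined, and was added for neural culture and single embryoid body days after the data were seen. edgeR and DESeq2 on the recovered reads were also chosen after the data were seen.

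Before the data were examined, 23 gene lists and 11 miRNA lists were written down from general knowledge. The gene lists covered naive pluripotency, core pluripotency, formative and primed epiblast, neural and ectoderm, neural crest, primitive streak and early mesoderm, cardiac and muscle mesoderm, and blood and endothelium. They also covered definitive endoderm, yolk sac and liver-type endoderm, trophectoderm, 2-cell-like state, fibroblast and feeder, cholesterol synthesis, fatty acid and triglyceride synthesis, fatty acid oxidation, PPAR targets, and PPAR receptors and partners. The last 5 were the microRNA pathway, reported miR-290 and miR-302 targets, p53 targets, stress and immediate early genes, and cell cycle. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the residuals. Members were also called with p-values adjusted over the list alone. For untested comparisons the list median was ranked among 10000 random lists matched for expression.

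Named genes followed a rule fixed before the data were examined. Dgcr8, Drosha and Pparg were always named, followed by up to 4 called members of each list with the largest fold changes. The 10 largest rises and the 10 largest falls among called genes with a mean level above that of the median gene were added. Outside the lists, a gene described as changing most or next is ranked among such genes only. Some genes that the rule selected are not reported here, though they count in the numbers of calls and in the list tests. Pparg was not analysed here in the GW9662 table, which did not list it. Sets of genes with miRNA seed matches were planned but not run, because no genome or 3' UTR sequence was available.

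Reads were simulated with known changes planted, to test the procedure. Each gene had its mean level in these libraries, the same in all of them, and a spread taken from the trend over levels. Changes were planted in genes with a mean of at least 50 and miRNAs with a mean of at least 100. Recovery at lower levels, in genes with a larger spread than the trend, or beside day effects was therefore not tested. Of 100 genes planted at 2-fold, limma recovered 97% in the ΔSL1 mESC comparison, 99% in the DGCR8-/- comparison and 97% between both mutants. The EpiLC comparisons recovered 90%, 90% and 91% at 6, 24 and 48 h, and embryoid bodies 100%. Of 100 genes planted at 4-fold, 100% were recovered in all 7. False calls among all calls ranged from 3.9% to 9.6% for genes and were 4.4% for miRNAs. Of 30 miRNAs planted at 2-fold 46.7% were recovered, and of 30 planted at 4-fold 96.7%.

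The work used R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.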

Results

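The libraries asked how mouse embryonic stem cells (mESC) of a genotype labelled ΔSL1 differ from wild-type (WT) cells and from cells labelled DGCR8-/-. They also followed both genotypes into embryoid bodies and neural culture, and ΔSL1 cells into epiblast-like cells (EpiLC). WT embryoid bodies treated with GW9662, a PPARγ antagonist, were also sequenced. The genotypes and times come from the labels, which do not spell out SL1, and 1 of the DGCR8-/- libraries is labelled DGCR9-/- in its genotype field. RNA-seq levels are reads per 10000000, and p-values measure only the spread between these samples, which may be technical.

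Dgcr8, which encodes the RNA-binding partner of Drosha, was the gene named in the labels and was checked first. In serum/LIF mESC it stood at 484.8 and 464.1 in the 2 WT libraries, at 1291 and 1419 in ΔSL1, and at 125.6 and 139.2 in DGCR8-/-. The limma log2 fold change was 1.51 (standard error 0.13, Benjamini-Hochberg adjusted p = 9.78e-08) in ΔSL1 and -1.84 (adjusted p = 6.03e-10) in DGCR8-/-. Both DGCR8-/- libraries were low in Dgcr8, so the label DGCR9-/- was read as a slip. In embryoid bodies Dgcr8 rose in ΔSL1 to 1380 ± 107 from 558.9 ± 45.7 (standard deviations over 4 days), a log2 fold change of 1.30 (limma, Benjamini-Hochberg adjusted p = 1.97e-04). In neural culture at day 6 it read 1085 in ΔSL1 and 605.7 in WT, with 1 library each. Drosha, the RNase of the Microprocessor, changed by -0.04 in ΔSL1 mESC (adjusted p = 0.853) and fell by 0.54 in DGCR8-/- (adjusted p = 0.00257; limma, Benjamini-Hochberg). Pparg was barely present in mESC, at 1.28 in ΔSL1 and 1.27 in WT, and was not called in DGCR8-/- either (log2 fold change -0.58, limma, Benjamini-Hochberg adjusted p = 0.213).

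**Figure D1:**
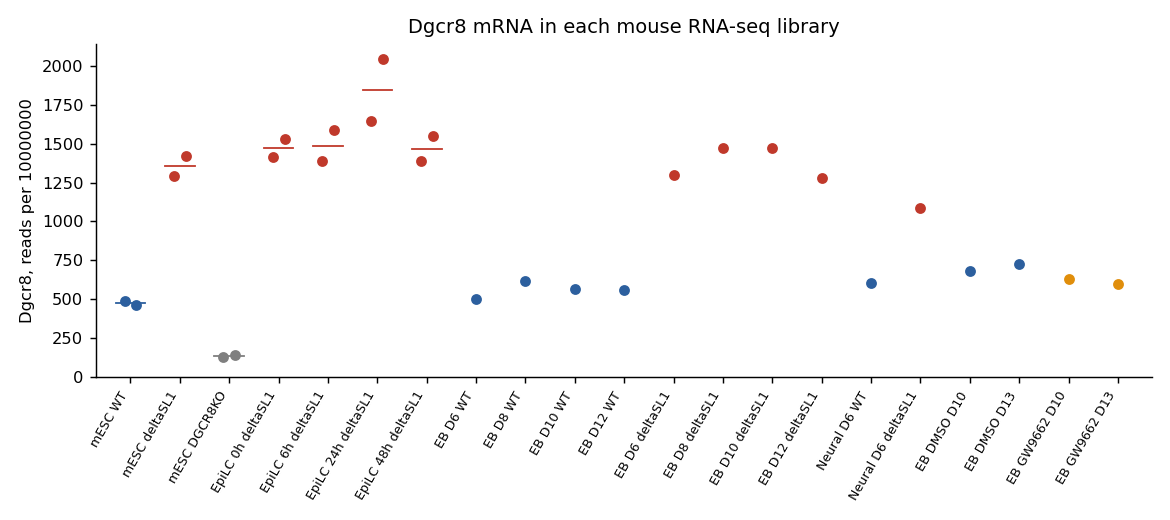
Dgcr8 mRNA in reads per 10000000 (vertical axis) for every mouse RNA-seq library, grouped by genotype, culture and time (horizontal axis). Each point is 1 library and bars are means of 2 libraries. ΔSL1 mESC stood at 1291 and 1419 against 484.8 and 464.1 in WT.

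ΔSL1 mESC raised Chac1, a glutathione-degrading enzyme induced by amino acid stress, to 973 ± 267 from 59.8 ± 19.0 in WT serum/LIF mESC (means and standard deviations of 2 libraries each). This was 16.1-fold, a log2 fold change of 4.01 with a standard error of 0.19 (limma, Benjamini-Hochberg adjusted p = 7.88e-11). The stress-induced chromatin protein gene Nupr1 (3.74), the BH3-only cell death gene Hrk (3.74), the glucocorticoid-induced gene Tsc22d3 (3.58) and the lipoprotein receptor gene Vldlr (3.48) rose next. Stc2 (3.16), a secreted stress-induced glycoprotein gene, the channel subunit gene Lrrc8d (3.13), the mTORC1 inhibitor gene Ddit4 (3.07), the leucine-rich repeat gene Lrrc31 (3.04) and the amino acid transporter gene Slc1a4 (3.03) completed the 10 largest rises among called genes with a mean level above that of the median gene. Among the falls, the growth regulator Myc dropped to 192.5 ± 20.5 from 746.8 ± 130, 3.85-fold lower (limma, Benjamini-Hochberg adjusted p = 1.47e-06), and the chaperone gene Hspa8 to 4536 ± 246 from 15543 ± 632. The noncoding transcript D7Ertd143e (-2.10), the 14-3-3 gene Sfn (-1.94), the homeobox gene Gbx2 (-1.89), the exocyst-like gene Exoc3l (-1.82), the intermediate filament gene Ina (-1.77), the bHLH gene Tcf15 (-1.69), Fam169a (-1.68), a gene of unclear function, and the growth factor gene Bmp4 (-1.51) also fell.

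In all, 6622 of 16239 genes were called between ΔSL1 and WT mESC by limma, 5297 up and 1325 down. The median of all genes stood at 0.28, and after scaling to the median ratio 6017 genes were called, 3403 up and 2614 down, so much of the excess of rises depended on the scaling. On recovered reads edgeR gave 3130 up and 2975 down, and DESeq2 turned the excess, with 2334 up and 2890 down. Without the 1st WT library the count dropped to 3916.

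Of 19 cholesterol synthesis genes in ΔSL1 mESC, 6 fell and 2 rose, and the same numbers held adjusted over the list alone. Idi1 (-1.17) and Fdps (-0.87) fell, whereas Cyp51 (0.69) rose. This was the only list that passed camera in this comparison (median -0.22, Benjamini-Hochberg adjusted p = 0.0211, adjusted p = 0.860 with an estimated correlation).

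Naive pluripotency genes rose for 11 of 15 and none fell in ΔSL1 mESC, or 11 and 1 adjusted over the list alone, yet camera did not call the list (Benjamini-Hochberg adjusted p = 0.226, adjusted p = 0.860 with an estimated correlation). The Krüppel-like factor genes Klf2 (1.23) and Klf5 (1.22), the kinase cofactor gene Tcl1 (1.11) and the nuclear receptor gene Nr0b1 (1.00) rose most. After median scaling 8 naive genes rose and 2 fell. Among p53 targets 10 of 12 rose, or 6 after median scaling, led by the sestrin gene Sesn2 (1.55), the cell death gene Bbc3 (1.39), the cyclin-dependent kinase inhibitor gene Cdkn1a (1.29) and the death receptor gene Eda2r (1.03), with a camera Benjamini-Hochberg adjusted p of 0.226 and adjusted p = 0.860 with an estimated correlation. Of 10 core pluripotency genes Sox2 rose (0.75) and Utf1 (-0.70) and Lin28a (-0.55) fell, with 4 down after median scaling. The list of reported miR-290 and miR-302 targets split, with 8 of 15 up and 4 down, including Txnip (1.88), Aff1 (1.81), Cdkn1a (1.29) and Lefty2, which fell, and turned to 4 up and 5 down after median scaling.

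Stress and immediate early genes rose for 6 of 12 and fell for 1 in ΔSL1 mESC, with Atf3 (3.43), Trib3 (2.33) and Ddit3 (2.28), which encode transcription factors and a pseudokinase of the integrated stress response, beside Chac1 (4.01). Fatty acid oxidation rose for 9 of 17 (Cpt1a 1.06, Acadl 0.89, Slc25a20 0.80), and PPAR targets rose for 6 of 14 and fell for 1 (Fgf21 3.12, Pdk4 1.37, Cidea 1.32, Lpl 1.23). Fatty acid and triglyceride synthesis had 6 of 20 up and 3 down, and PPAR receptors and partners 2 of 9 up and 2 down. In the microRNA pathway 5 of 14 rose, including the Argonaute genes Ago4 (1.29) and Ago2 (0.93) and the GW182 gene Tnrc6c (1.18). Formative genes split 3 and 3 of 11, with Otx2 (2.03) and Cdh2 (1.08) up and Dnmt3b (-1.13) and Foxd3 (-0.77) down.

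Among lineage lists in ΔSL1 mESC, neural genes rose for 5 of 16 and fell for 3 (Dll1 2.51, Nes -1.22), and after median scaling 2 rose and 4 fell. Neural crest had 3 of 7 up and 1 down, the primitive streak 1 of 10 up (Wnt3 1.21) and 3 down (Wnt3a -1.42, Evx1 -1.27, Eomes -0.86), and cardiac mesoderm 5 of 14 up. Blood and endothelium had 3 of 10 up and 1 down (Tek 2.01, Pecam1 0.77), definitive endoderm 2 of 10 up (Prdm1 2.48, Cxcr4 1.38), and yolk sac endoderm 4 of 12 up and 1 down. Trophectoderm had 3 of 9 up (Gata3 1.68, Tfap2c 1.23), the 2-cell-like list 1 of 4 up (Zscan4c), fibroblast genes 4 of 7 up (Fn1 1.54) and 1 down (Vim -0.96), and cell cycle 1 of 17 up and 1 down. The formative, neural, trophectoderm, 2-cell-like and miRNA target lists had a median and a mean above 0 but a camera direction below 0, because camera ranks a list against all genes. The primitive streak list had a median of 0.09 and a mean of -0.16, and fatty acid synthesis a median of -0.01 and a mean of 0.10, both with a camera direction below 0. Median scaling turned fatty acid synthesis from 6 up and 3 down to 4 up and 5 down, and PPAR receptors from 2 and 2 to 0 up and 3 down. It left 3 cardiac genes up, gave trophectoderm 2 up and 2 down, cell cycle 1 up and 3 down, and cholesterol synthesis 1 up and 9 down. It also moved the medians of the primitive streak, 2-cell-like, microRNA pathway and cell cycle lists below 0.

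Cells without DGCR8 raised Mid1, which encodes a microtubule-bound ubiquitin ligase, to 2614 ± 190 from 7.63 ± 0.56 in WT (2 libraries each), 303-fold (limma, Benjamini-Hochberg adjusted p = 4.23e-16). The Hedgehog-binding protein gene Hhip (7.04), Lrrc31 (6.34), the protocadherin-like gene Fat2 (6.13) and the lipid enzyme gene Cds1 (5.77) followed. Further rises were Megf11 (5.24), an adhesion gene, Lrrc15 (5.19), a leucine-rich repeat gene, the miRNA host transcript Mirc35hg (5.18), the muscle methyltransferase gene Smyd1 (5.02) and the lysyl oxidase gene Loxl4 (4.92). Myc fell almost to absence, at 4.96 ± 1.95 against 746.8 ± 130 (log2 fold change -7.00, limma, Benjamini-Hochberg adjusted p = 7.41e-15). The growth cone gene Gap43 (-6.08), the phospholipase gene Pla2g1b (-5.10), the POU factor gene Pou2f3 (-4.98), the endocytic receptor gene Cubn (-4.85), the steroid enzyme gene Cyp11a1 (-4.48), Bmp4 (-4.42), Gbx2 (-4.30) and the imprinted gene Peg10 (-4.13) fell as well.

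Reported miR-290 and miR-302 targets rose for 14 of 15 in DGCR8-/- mESC and 1 fell, with the same counts adjusted over the list alone (camera, median 1.58, Benjamini-Hochberg adjusted p = 0.0123, adjusted p = 0.870 with an estimated correlation). The Nodal antagonist gene Lefty1 reached 3134 ± 548 from 213.6 ± 39.8 (3.87), the thioredoxin-binding gene Txnip (3.29) and the Hippo kinase gene Lats2 (3.18) rose, and the Wnt antagonist gene Dkk1 (-3.21) fell. No other list passed camera after adjustment. The nearest were fatty acid oxidation, core pluripotency and cell cycle, each with a camera Benjamini-Hochberg adjusted p of 0.0777, and with adjusted p = 0.883 with an estimated correlation for fatty acid oxidation, 0.870 for core pluripotency and 0.936 for cell cycle. Fatty acid oxidation had 14 of 17 up (Cpt1a 2.96, Slc25a20 2.08), core pluripotency 2 of 10 up (Sox2 0.84) and 7 down (Lin28a -2.74, Trim71 -1.07, Utf1 -0.96), and cell cycle 3 of 17 up and 9 down (Mcm5 -1.06, Pcna -0.88).

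Among the remaining lists in DGCR8-/- mESC, naive pluripotency had 6 of 15 up (Klf2 3.09, Fgf4 1.66, Prdm14 1.63) and 5 down (Dppa3 -1.39), and formative genes 5 of 11 up (Zic2 4.27, Otx2 4.12) and 4 down. Neural genes had 11 of 16 up (Pax6 2.37) and 1 down, neural crest 2 of 7 up and 1 down, primitive streak 5 of 10 up and 3 down, and cardiac mesoderm 7 of 14 up and 3 down (Myl4 -3.76). Blood and definitive endoderm each had 5 of 10 up and 4 down, yolk sac endoderm 4 of 12 up and 4 down (Cubn -4.85, Dab2 -4.83, Hnf4a -3.92), trophectoderm 2 of 9 up and 3 down, the 2-cell-like list 3 of 4 down, and fibroblast genes 3 of 7 up and 2 down. Cholesterol synthesis had 10 of 19 up and 3 down, fatty acid and triglyceride synthesis 8 of 20 up (Mlxipl 2.90) and 6 down, PPAR targets 7 of 14 up (Pdk4 3.37, Fgf21 3.23) and 1 down, and PPAR receptors 3 of 9 up and 2 down. The microRNA pathway had 10 of 14 up (Ago4 2.43, Ago1 2.14, Tnrc6c 1.74) and 4 down, p53 targets 6 of 12 up and 3 down, and stress genes 8 of 12 up. In total 10671 genes were called by limma, 6850 up and 3821 down. With the median of all genes at 0.279, median scaling gave 5530 up and 5174 down (DESeq2 on recovered reads 4718 and 4833) and turned the fatty acid synthesis list from 8 up and 6 down to 7 up and 10 down and the blood list from 5 up and 4 down to 4 up and 5 down. It gave neural genes 9 up and 3 down, cholesterol synthesis 7 and 5, fatty acid oxidation 11 and 2, core pluripotency 1 and 8, and cell cycle 0 and 11. The naive, formative, primitive streak, definitive endoderm and PPAR receptor lists had medians above 0 but a camera direction below 0. Blood had a median of 0.15 and a mean of -0.11, and fatty acid synthesis a median of -0.03 and a mean of 0.22, both with a camera direction below 0.

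Compared directly, DGCR8-/- exceeded ΔSL1 mESC most in Mid1 (7.33) and in D7Ertd143e, at 5044 against 58.5 (6.55). The retrotransposon-derived gene Rtl1 (5.09), Hhip (4.60), Lefty1 (4.51) and the miR-17/92 host transcript Mir17hg (4.03) were also higher. Gap43 (-5.75), Pla2g1b (-5.57), Pou2f3 (-5.22), Myc (-5.06, 4.96 against 192.5), Peg10 (-4.93, 149.2 against 4605), the citrate transporter gene Slc13a5 (-4.57), Cubn (-3.90) and Cyp11a1 (-3.84) were lower. The reported miR-290 and miR-302 targets had 12 of 15 higher in DGCR8-/- and 1 lower, with the same counts adjusted over the list alone (camera, median 1.36, Benjamini-Hochberg adjusted p = 0.00114, adjusted p = 0.751 with an estimated correlation). Cholesterol synthesis had 12 of 19 higher and 2 lower, neural genes 10 of 16 higher and 2 lower, fatty acid oxidation 8 of 17 higher (Cpt1a 1.90) and 1 lower, and the microRNA pathway 6 of 14 higher (Ago1 2.23) and 4 lower. Naive genes had 3 of 15 higher and 6 lower (Klf5 -2.35, Tbx3 -1.55), core pluripotency 4 of 10 lower (Lin28a -2.19), p53 targets 6 of 12 lower and cell cycle 2 of 17 higher and 10 lower, none of which passed camera. The other lists did not pass either: formative genes had 5 of 11 higher and 3 lower, neural crest 1 of 7 and 2, primitive streak 3 of 10 and 3, cardiac mesoderm 4 of 14 and 5, blood 3 of 10 and 6, definitive endoderm 4 of 10 and 4, and yolk sac endoderm 1 of 12 and 5. Trophectoderm had 3 of 9 higher and 5 lower, the 2-cell-like list 0 of 4 and 3, fibroblast genes 2 of 7 and 4, fatty acid synthesis 7 of 20 and 4, PPAR targets 6 of 14 and 3, PPAR receptors 4 of 9 and 3, and stress genes 4 of 12 and 4. Median and mean differed in sign for definitive endoderm (0.60 and -0.15), fatty acid synthesis (-0.01 and 0.12), PPAR receptors (-0.12 and 0.18) and stress genes (-0.06 and 0.09). Of 9399 genes called by limma, 4760 were higher and 4639 lower in DGCR8-/-, a near-even split that median scaling turned to 4589 and 4909.

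The ΔSL1 and DGCR8-/- changes shared 3608 genes up and 894 down against the same 2 WT libraries, where independent lists would share 2234.4 and 311.8. A further 411 genes rose in ΔSL1 and fell in DGCR8-/-, and 137 did the reverse. The covariance of the log2 fold changes was 0.396, and 0.03 in 50 simulations of unchanged groups sharing the WT libraries, which gave 0.02 same-sign calls on average. The correlation was 0.487 (0.501 in the simulations), with the same sign in 70.5% of genes (66.7%). The simulated groups held no changed genes, so few same-sign calls were bound to follow there. The WT libraries could not be divided while keeping 2 per comparison, so part of the excess may come from the shared controls. Part may also come from scaling, since the median of all genes was 0.28 in ΔSL1 and 0.279 in DGCR8-/-. The overlap was not recomputed after median scaling.

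Summed miRNA levels of ΔSL1 mESC were 522996 ± 8288 against 938204 ± 87393 in WT as deposited, 55.7% of WT (2 libraries each, exact permutation p = 0.333, the smallest possible). The epithelial miRNA miR-200b-3p fell most among well-expressed miRNAs, to 349.8 ± 58.7 from 1884 ± 590 (-2.40, standard error 0.28, limma, Benjamini-Hochberg adjusted p = 0.0120). The miR-181c-3p (-2.26), miR-200c-3p (-2.25), miR-484 (-2.12), miR-199a-3p (-2.07), miR-543-3p (-1.95), miR-23a-3p (-1.90), miR-129-5p (-1.90) and miR-369-3p (-1.87) fell too. The oncogenic cluster member miR-17-5p reached 906 ± 45.0 from 3644 ± 843 (-1.99, limma, Benjamini-Hochberg adjusted p = 0.0107). Only miR-381-3p of the imprinted Dlk1-Dio3 cluster rose, to 5072 from 3361 ± 342 (0.60, limma, Benjamini-Hochberg adjusted p = 0.0306).

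The calls of lower miRNAs depended on the factor the depositors applied to each library. Of 383 miRNAs 168 were called with deposited values (1 up, 167 down, median of all -0.925), but 2, both up, after median scaling, and 1 after scaling each library to its own miRNA total. The calls ended because folds shrank by about the factor. Some stayed over 2-fold after median scaling, for example those of miR-200b-3p (-1.46), miR-181c-3p (-1.33) and miR-200c-3p (-1.30) (limma, Benjamini-Hochberg adjusted p = 0.126 each). Scaling to the miRNAs that do not need the Microprocessor gave 25 calls, all up. Without the 1st or the 2nd ΔSL1 library 99 and 56 miRNAs were called.

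By list, all 12 tested members of the miR-290 cluster, the main miRNAs of mESC, were lower in ΔSL1 and 8 fell (median -0.70), with miR-292a-5p at 51% and miR-293-5p at 65.3% of WT. The fixed list did not match the name miR-290a, so the counts and shares of this cluster leave miR-290a out. The miR-302 cluster had 0 of 4 calls (0.23), the let-7 family 4 of 8 down (-1.40), the miR-17/92 and paralogous clusters 15 of 20 down (-1.11), neural miRNAs 3 of 10 down (-0.60), and the miR-200 family 5 of 6 down (-1.83). The Microprocessor-independent miRNAs, which should not need DGCR8, fell for 4 of 5 (-1.73), including miR-320-3p (-1.50), miR-344-3p (-2.14) and miR-484 (-2.12). The Dlk1-Dio3 cluster had 1 of 60 up and 22 down (-0.72), the Sfmbt2 cluster 1 of 22 down (-0.80), other abundant miRNAs 19 of 40 down (-0.87), tissue and lineage miRNAs 9 of 14 down (-1.17), and miRNAs in no list 77 of 182 down. As shares of miRNA reads, the miR-290 cluster held 62.3% and 62.5% in ΔSL1 and 58.5% and 61.1% in WT. The miR-200 family held 0.258% and 0.224% against 0.444% and 0.635%, and let-7 0.135% and 0.153% against 0.178% and 0.180%. The log2 share differed by -1.14 (standard error 0.28) for the miR-200 family, -0.31 (0.09) for let-7, -0.24 (0.16) for miR-17/92 and 0.06 (0.03) for miR-290. For the Microprocessor-independent miRNAs it differed by -0.85 (0.49). The log2 ratio of all other miRNAs to the Microprocessor-independent ones was 9.33 and 9.34 in ΔSL1 and 8.00 and 8.98 in WT.

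**Figure D2:**
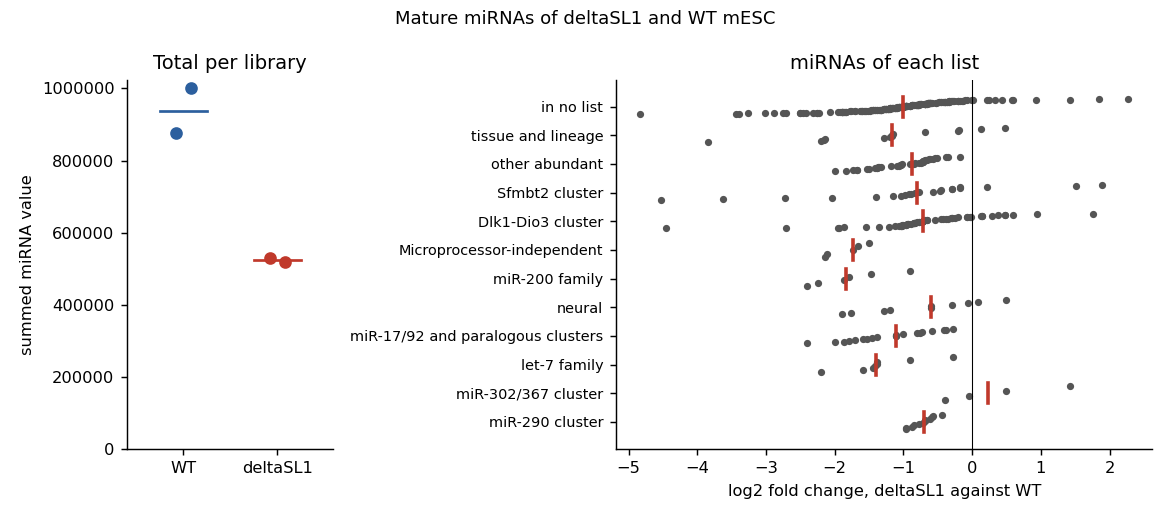
Summed miRNA value per library (left, each point 1 library) and log2 fold change of ΔSL1 against WT mESC for each tested miRNA, by list (right, each point 1 miRNA, red bars medians). The total was 55.7% of WT, and the list medians ran from -1.83 for the miR-200 family to 0.23 for the miR-302 cluster.

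EpiLC induction of ΔSL1 cells lowered naive genes within 48 h. Klf4, a naive pluripotency factor gene, fell to 49.4 ± 14.1 at 48 h from 1813 ± 217 at 0 h (-5.19, 2 libraries each, limma, Benjamini-Hochberg adjusted p = 2.38e-07), and the T-box gene Tbx3 to 27.1 ± 7.58 from 1414 ± 100 (-5.68, adjusted p = 1.08e-07). The POU factor gene Pou3f1 rose to 671.8 ± 4.48 from 5.73 ± 0.522 (6.65, limma, Benjamini-Hochberg adjusted p = 1.53e-07) and the epiblast growth factor gene Fgf5 to 321.4 from 0.134 (8.16). WT EpiLC were not analysed here, so these changes describe ΔSL1 cells alone. Dgcr8 changed by 0.01, 0.32 and -0.01 at 6, 24 and 48 h, and Drosha rose by 0.36, 0.40 and 0.34 (limma, Benjamini-Hochberg adjusted p = 0.0203, 0.0118 and 0.0170).

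At 6 h in EpiLC medium the phospholipase gene Pla2g7 (6.75), the ERK feedback gene Spry4 (6.69), the Wnt ligand gene Wnt7b (6.59), the calcium-binding gene S100a6 (6.20), the filamin gene Flnc (6.19) and the FGF-binding gene Fgfbp1 (5.61) rose most, with Thbs1 (5.24), Phlda1 (5.06) and Etv4 (4.61), a matrix, an apoptosis-linked and an ETS factor gene. The LIF-STAT3 feedback gene Socs3 fell to 112 ± 17.5 from 1147 ± 138 (-3.35), as did the hypoxia-linked genes Bnip3 (-4.70), Slc16a3 (-3.36) and Egln3 (-2.29), the channel gene Trpm1 (-3.28), the phosphorylase gene Upp1 (-2.92) and the Wnt effector gene Lef1 (-2.37). At 24 h the ERK phosphatase gene Dusp6 reached 528.6 ± 40.6 from 20.5 ± 3.21 (4.63, limma, Benjamini-Hochberg adjusted p = 6.60e-07), behind Myrf (5.59), Etv4 (5.44), Spry4 (5.41) and Enpp2 (5.40), while the protease inhibitor gene A2m (-5.75), the water channel gene Aqp3 (-5.28), Trpm1 (-5.27), S100a13 (-4.86), Socs3 (-4.32) and the receptor gene Kit (-3.85) fell. At 48 h Enpp2, the gene of the lysophospholipase autotaxin, was highest, at 981.6 ± 299 from 1.42 ± 0.275 (8.64, limma, Benjamini-Hochberg adjusted p = 5.92e-07). It was followed by the carbonic anhydrase gene Car4 (8.34), the metalloproteinase gene Mmp25 (7.83), Myrf (7.22), the endocytic receptor gene Lrp2 (6.22) and the membrane glycoprotein gene Emb (5.43). Aqp3 (-8.14), Trpm1 (-6.76), the junction gene Jam2 (-5.75), the netrin gene Ntn1 (-5.41) and Mitf (-4.92) fell.

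The naive pluripotency list fell for 5 of 15 and rose for 2 at 6 h, fell for 12 and rose for 2 at 24 h, and fell for 14 and rose for 1 at 48 h (Klf4 -1.82, -2.47 and -5.19, Tfcp2l1 -1.22, -2.57 and -4.46). Adjusted over the list alone, 6, 12 and 14 fell and 3, 3 and 1 rose. Camera called the list at 24 h (median -1.14, Benjamini-Hochberg adjusted p = 2.31e-04, adjusted p = 0.122 with an estimated correlation) and at 48 h (median -3.61, camera adjusted p = 2.46e-11, adjusted p = 0.0377 with an estimated correlation). Formative genes rose for 4 of 12 and fell for 1 at 6 h, and rose for 10 at 24 h (camera, median 1.79, Benjamini-Hochberg adjusted p = 5.51e-06, adjusted p = 0.122 with an estimated correlation) and 11 at 48 h (camera, median 4.18, adjusted p = 4.74e-08, adjusted p = 0.0381 with an estimated correlation). Adjusted over the list alone 5, 10 and 12 rose and 1, 0 and 0 fell. Sox3 (5.65) and Lef1 (4.69) rose at 48 h and Otx2 (2.51) at 24 h.

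Core pluripotency rose for 6 of 10 and fell for 1 at 6 h (camera, median 0.90, Benjamini-Hochberg adjusted p = 0.00632, adjusted p = 0.309 with an estimated correlation), for 7 with 1 down at 24 h (camera, median 0.69, adjusted p = 0.0200, adjusted p = 0.275 with an estimated correlation) and for 4, with 3 down, at 48 h. Adjusted over the list alone 7, 7 and 4 rose and 1, 1 and 3 fell. Utf1 rose by 2.29, 2.90 and 2.68 and Lin28a by 1.30, 2.36 and 2.58, while Sox2 fell by 1.24 at 48 h. Cholesterol synthesis rose for 3 of 19 and fell for 1 at 6 h, and rose for 10 at 24 h (camera, median 0.49, Benjamini-Hochberg adjusted p = 0.00269, adjusted p = 0.515 with an estimated correlation) and all 19 at 48 h (camera, median 0.91, adjusted p = 3.65e-06, adjusted p = 0.380 with an estimated correlation), with the same 3, 10 and 19 adjusted over the list alone. At 48 h Lss (1.66), Dhcr7 (1.28) and Fdps (1.25) were among them.

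Fatty acid oxidation fell for 9 of 16 at 6 h, or 11 adjusted over the list alone (camera, median -0.47, Benjamini-Hochberg adjusted p = 0.00632, adjusted p = 0.309 with an estimated correlation), for 5 with 2 up at 24 h, and for 8 with 3 up at 48 h, or 10 and 3 adjusted over the list alone (camera, median -0.40, adjusted p = 0.0387, adjusted p = 0.327 with an estimated correlation). Cpt1a, the gene of the carnitine transferase that admits fatty acids to mitochondria, fell by 1.80, 2.47 and 1.72, Slc25a20 by 2.13 at 48 h, and Acadl rose (1.43). Definitive endoderm fell for 3 of 8 at 48 h, the same adjusted over the list alone (Gata6 -2.38, camera median -0.52, Benjamini-Hochberg adjusted p = 0.0498, adjusted p = 0.378 with an estimated correlation). Cell cycle genes rose for 9 of 17 at 24 h, or 11 adjusted over the list alone and 5 after median scaling (Aurkb 0.71, Plk1 0.69, camera median 0.35, Benjamini-Hochberg adjusted p = 0.00570, adjusted p = 0.177 with an estimated correlation), and for 5 after median scaling.

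The other lists did not pass camera during EpiLC induction, and their counts at 48 h were as follows. Neural genes had 4 of 14 up (Dll1 5.30, Sox11 3.54) and 4 down, neural crest 3 of 8 up and 2 down, primitive streak 1 of 11 up and 4 down, cardiac mesoderm 1 of 11 up and 4 down, and blood 3 of 10 up and 4 down (Runx1 -4.23). Yolk sac endoderm had 5 of 11 up (Cubn 3.40, Dab2 1.98), trophectoderm 2 of 9 up and 5 down (Tfap2c -4.13), fibroblast genes 5 of 8 up and 2 down, and fatty acid synthesis 7 of 20 up (Acsl4 2.44) and 3 down. PPAR targets had 2 of 12 up and 3 down, with a median of 0.24 but a camera direction below 0, and PPAR receptors 3 of 8 up. The microRNA pathway had 6 of 14 up (Lin28b 1.33) and 1 down, miR-290 and miR-302 targets 3 of 15 up (Lefty1 3.77) and 4 down, p53 targets 5 of 12 up and 2 down, and stress genes 5 of 12 up (Egr1 3.76) and 1 down.

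limma called 4543 of 15398 genes at 6 h (2249 up, 2294 down), 4716 at 24 h (2711 up, 2005 down) and 6524 at 48 h (3668 up, 2856 down). This fit did not use the ΔSL1 number that the titles carry through all times. With that number as a block the counts were 6519, 6699 and 8195. Median scaling turned the 6 h split to 2361 up and 2236 down, the 24 h split to 2252 up and 2347 down, and fatty acid synthesis at 24 h from 3 up and 2 down to 2 up and 3 down. Median and mean differed in sign for the primitive streak (-0.09 and 0.28) and the miRNA targets (-0.09 and 0.10) at 6 h, for cardiac mesoderm (0.04 and -0.32) at 24 h and for the miRNA targets (-0.16 and 0.12) at 48 h. Cardiac genes at 6 h (median 0.25) and blood genes at 24 h (0.22) had a camera direction below 0. The 6 h count dropped to 2495 without the 1st 6 h library, 2514 without the 2nd and 2526 without the 2nd 0 h library, and the 24 h count to 3131 without the 1st 0 h library.

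**Figure D3:**
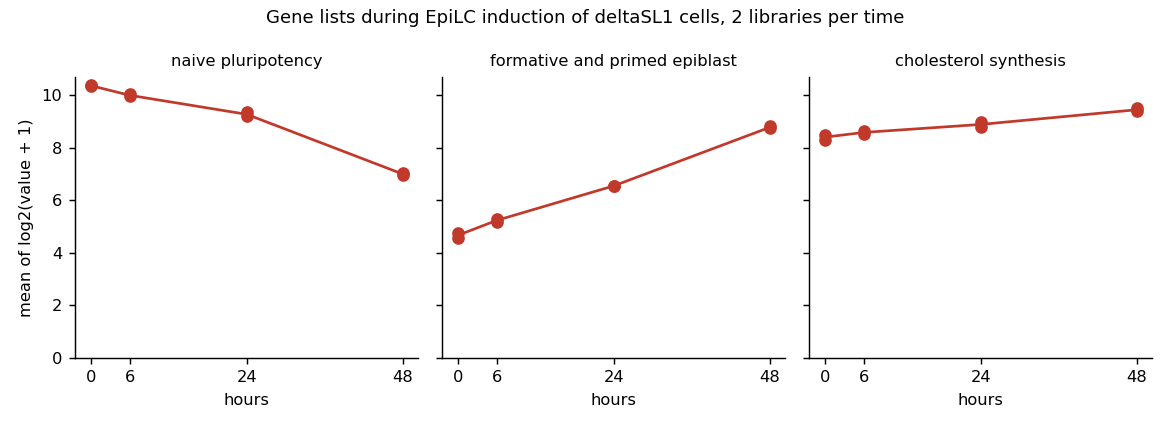
Mean of log2(value + 1) over the members of 3 gene lists (vertical axis) against hours of EpiLC induction in ΔSL1 cells (horizontal axis). Each point is 1 library and lines join means of 2. Naive genes went from 10.4 and 10.34 to 7.04 and 6.96, and formative genes from 4.76 and 4.57 to 8.74 and 8.82.

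Embryoid bodies of ΔSL1 cells raised Afp, the fetal serum protein gene of yolk sac endoderm, to 253 ± 197 from 10.4 ± 8.23 in WT (4 days each, 1 library per day), 18.8-fold with a log2 standard error of 0.90 (limma, Benjamini-Hochberg adjusted p = 0.00862). All 4 ΔSL1 libraries carry the same SLKO number in their deposited names. What the number marks is not given in the sources used here. If it marks a cell line, genotype and line cannot be told apart in embryoid bodies. The apolipoprotein gene Apob rose to 483.5 ± 158 from 72.2 ± 66.9 (3.25, limma, Benjamini-Hochberg adjusted p = 0.00167), with the retinol carrier gene Rbp4 (2.74), the receptor gene Cubn (2.54), the cathepsin gene Ctsh (2.53), the channel gene Clic6, the X-inactivation RNA gene Xist (1.94), the lysosomal gene Laptm5 (1.77), the Hoxa-linked noncoding gene Halr1 (1.64) and the protease gene Tmprss2 (1.53). The neural POU factor gene Pou3f2 fell to 25.8 ± 35.8 from 267 ± 235, 11.8-fold lower (limma, Benjamini-Hochberg adjusted p = 5.57e-04), and the neurofilament gene Nefm to 99.0 ± 103 from 896.1 ± 896 (-2.71). The orphan receptor gene Nr2f1 (-3.01), Ildr2 (-2.89), Fat4 (-2.87), the retinoic acid hydroxylase gene Cyp26b1 (-2.82), Prr36 (-2.63), Dach1 (-2.59), Nhlh1 (-2.55) and Nhlh2 (-2.54), the last of them neuronal bHLH genes, fell as well. Drosha (0.18, adjusted p = 0.235) and Pparg (0.25, adjusted p = 0.682) were not called (limma, Benjamini-Hochberg). Pparg was barely present, at 0.908 to 5.17 per library.

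Yolk sac and liver-type endoderm rose for 16 of 17 genes in ΔSL1 embryoid bodies, and for 17 adjusted over the list alone, including Apoa4, next to Afp the member with the largest change, and Fgb (3.25). Camera put the list median at 2.74 (Benjamini-Hochberg adjusted p = 1.23e-13, adjusted p = 0.616 with an estimated correlation). Neural and ectoderm genes fell for 20 of 23 and rose for 1, with the same counts adjusted over the list alone (camera, median -1.68, Benjamini-Hochberg adjusted p = 1.06e-04, adjusted p = 0.634 with an estimated correlation). The Notch effector gene Hes5 (-3.21), the proneural gene Neurog1 (-3.12) and the forebrain gene Lhx2 (-2.60) were among those that fell. The mean log2 level of neural genes climbed from 4.8 at day 6 to 8.38 at day 12 in WT and from 4.05 to 6.74 in ΔSL1, while yolk sac genes went from 4.4 to 3.01 in WT and from 5.35 to 6.01 in ΔSL1.

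**Figure D4:**
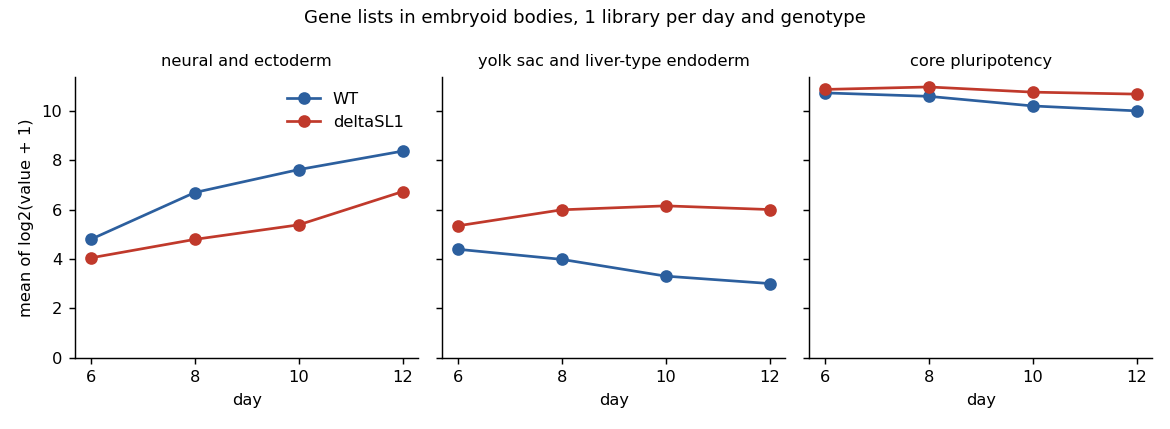
Mean of log2(value + 1) over the members of 3 gene lists (vertical axis) against day of embryoid body culture (horizontal axis) in WT (blue) and ΔSL1 (red). Each point is 1 library. At day 12 neural genes stood at 6.74 in ΔSL1 and 8.38 in WT, and yolk sac genes at 6.01 and 3.01.

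Core pluripotency rose for 5 of 10 genes in ΔSL1 embryoid bodies (Tdgf1 1.04, Dppa5a 1.02, Utf1 0.62, Pou5f1 0.59), the same adjusted over the list alone (camera, median 0.34, Benjamini-Hochberg adjusted p = 7.49e-05, adjusted p = 0.616 with an estimated correlation). Naive genes rose for 8 of 15 (Tbx3 1.28, Nr0b1 0.99, Klf4 0.91) and Dppa3 fell (-1.30), or 8 and 2 adjusted over the list alone (camera, median 0.35, Benjamini-Hochberg adjusted p = 1.06e-04, adjusted p = 0.616 with an estimated correlation). p53 targets rose for 7 of 12, or 8 adjusted over the list alone (Phlda3 0.83, Pmaip1 0.81, Eda2r 0.73, Cdkn1a 0.70, camera median 0.41, Benjamini-Hochberg adjusted p = 2.56e-06, adjusted p = 0.616 with an estimated correlation). The 2-cell-like list rose for 1 of 6 (Zfp352 1.84), or 4 adjusted over the list alone (camera median 1.08, Benjamini-Hochberg adjusted p = 0.00210, adjusted p = 0.616 with an estimated correlation). Trophectoderm rose for 2 of 9 (Gata3 1.19, Cdx2 0.98), or 4 adjusted over the list alone (camera median 0.50, Benjamini-Hochberg adjusted p = 0.00297, adjusted p = 0.616 with an estimated correlation). PPAR targets rose for 4 of 15 (Fabp1 2.03, Cidec 1.48) and fell for 2 (Lpl -0.64), the same adjusted over the list alone (camera median 0.16, Benjamini-Hochberg adjusted p = 0.0139, adjusted p = 0.616 with an estimated correlation).

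The remaining lists did not pass camera in embryoid bodies. Formative genes had 2 of 12 up and 6 down (Cdh2 -2.10, Sox3 -1.92), neural crest 5 of 10 down (Pax7 -2.38, Ednrb -2.30), primitive streak 2 of 12 up and 1 down, cardiac mesoderm 2 of 17 up and 3 down (Mef2c -1.89), blood 2 of 11 up and 2 down, and definitive endoderm 2 of 11 up and 1 down (Cxcr4 -2.26). The cardiac and blood lists had medians of -0.33 and -0.26 but a camera direction above 0, as had PPAR receptors (-0.07) and fatty acid oxidation. The primitive streak had a median of 0.07 and a mean of -0.12. Fibroblast genes had 3 of 9 down, cholesterol synthesis 7 of 19 down, fatty acid synthesis 2 of 20 up and 7 down, fatty acid oxidation 1 of 17 up and 3 down, and PPAR receptors 2 of 10 down. The microRNA pathway had Dgcr8 up and 7 of 14 down (Ago4 -1.31, Lin28b -1.19), miR-290 and miR-302 targets 3 of 15 up and 5 down, stress genes 5 of 12 down (Egr1 -1.08), and cell cycle 6 of 17 down (Mki67 -0.41, Top2a -0.40). Median scaling turned fatty acid oxidation to 5 up and 2 down, the miRNA targets to 5 up and 4 down, and cell cycle to 2 up and 0 down. It gave definitive endoderm 5 up and 1 down, trophectoderm 5 up, the 2-cell-like list 3 up, and fatty acid synthesis 3 up and 4 down.

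Of 16943 genes in embryoid bodies limma called 5318, 1112 up and 4206 down. The median of all genes was -0.158, and median scaling gave 4747 calls, 2100 up and 2647 down. Without a day factor 1178 genes were called (256 up, 922 down). Leaving out day 8, 10 or 12 left 2780, 2579 and 3370 calls. The days are not independent cultures, so the test measures steadiness over days. Per day, 237 genes differed at least 2-fold on all 4 days, 24 higher and 213 lower in ΔSL1 (41 and 152 after median scaling, and 128 in all with a pseudocount of 5).

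Neural culture at day 6 held 1 library per genotype, without replicates, so nothing was tested and the values describe these 2 libraries. ΔSL1 read lower in Miat, a neuronal noncoding RNA (99.7 against 1128, 11.2-fold lower), in the neurofilament genes Nefm (96.2 against 922.6, 9.50-fold lower) and Nefl (204.2 against 1227), in the contactin gene Cntn2 (84.3 against 674.2) and in the filament gene Ina (108.2 against 505.8). The homeobox gene Hoxb9 (296.1 against 1039), the imprinted gene Grb10 (1258 against 4183), Sox11 (156.8 against 499.1) and the tubulin gene Tubb3 (266.8 against 794.6) were lower too. Zfp352, a 2-cell-stage gene (911.5 against 237), Lrrn4 (501.3 against 162.2), the arginase gene Arg1 (765.7 against 292.1) and the endothelial receptor gene Tie1 (1319 against 512.2) read higher.

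Neural genes at day 6 of neural culture were at least 2-fold lower for 13 of 15 (median -1.57, percentile 0.0 of random lists), for example Neurog2 (7.51 against 95.8), Dcx (18.6 against 154.5), Olig2 (15.0 against 85.0) and Elavl3 (31.4 against 161.3). Yolk sac genes were at least 2-fold higher for 9 of 13 (1.10, percentile 100), with Apoa1 (177 against 18.2), Afp (56.3 against 10.2), Ttr (146.3 against 30.5) and Apob (180.1 against 33.5). All 6 of the 2-cell-like genes were higher (1.27, percentile 100), among them Zscan4c (487.6 against 231.5) and Usp17lc (383 against 127.8). Naive (0.41, percentile 100) and core pluripotency (0.22, percentile 99.9) medians were above 0, and formative (-0.79, percentile 0.14), stress (-0.76, percentile 0.0), fibroblast (-0.70, percentile 0.02) and miR-290 and miR-302 target medians (-0.37, percentile 1.8) were below. Dgcr8 differed by 0.84, Drosha by -0.12, and Pparg read 17.0 against 14.4. Of 11107 genes 162 were at least 2-fold higher and 361 lower, with a median of -0.153, or 218 and 234 after median scaling. Doubling the level minimum left 333 of these 523 genes.

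WT embryoid bodies in 20 µM GW9662 read lower in neural genes than those in DMSO at days 10 and 13, with 1 library per day and treatment. The fold changes below carry no test, while an additive fit of day and treatment, which leaves 1 residual degree of freedom, called 4089 genes by limma (902 up, 3187 down, Benjamini-Hochberg). Cyp26b1, a retinoic acid hydroxylase gene, read 27.8 against 570.1 at day 10 and 132.3 against 2002 at day 13. The retinoic acid carrier gene Crabp1 (115.5 against 1643, then 170 against 1727), the laminin gene Lama1 (141.4 against 2597, then 290.3 against 1800) and the glial lipid carrier gene Fabp7 (13.0 against 190.7, then 174.7 against 874.6) were lower too. The tight junction gene Cldn6 read higher (2.40-fold, then 4.21-fold), as did the contractile gene Tagln (2.31-fold, then 3.87-fold), and the oxidative stress response genes Nqo1 (2.57-fold, then 3.16-fold) and Gclm (2.23-fold, then 2.72-fold). Dgcr8 read 630.2 and 595.0 with GW9662 and 679.2 and 724.4 with DMSO.

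Neural genes were at least 2-fold lower on both days for 12 of 19 (median -2.19, percentile 0.0), for example Dcx (7.41 against 117.8, then 52.2 against 553.9) and Pax6 (83.3 against 255.2, then 138.8 against 386.6). Neurog1 and Neurog2 were listed at 0 with GW9662 at day 10, so no fold is given. Neural crest genes were lower for 5 of 7 (-3.32, percentile 0.0), with Pax7 at 1.48 against 47.8 and 7.97 against 126.3. Yolk sac genes were lower for 4 of 8 (-1.86, percentile 0.0), including Afp (43.0 against 326.9, then 5.07 against 194.7) and Ttr (1.48 against 101.5, then 11.6 against 80.7). Core pluripotency (0.34, percentile 99.99) and formative genes (0.31, percentile 99.99) were higher in the median, with Fgf5 at 318.8 against 84.8 and 230.8 against 36.1. Only 6 of 21 PPAR targets (-0.20, percentile 45.7) and 6 of 10 PPAR receptors (-0.38, percentile 5.72) reached the level minimum. Their medians lay within the range of random lists, as did those of fatty acid oxidation (-0.02, percentile 77.4) and cholesterol synthesis (-0.05, percentile 41.8). Medians were also above 0 for p53 targets (0.29, percentile 99.98) and 3 primitive streak genes (0.98, percentile 99.83, mean 0.40). The same held for 4 cardiac genes (0.63, percentile 99.79) and 5 trophectoderm genes (0.54, percentile 99.96). Trophectoderm stood at -0.02 at day 10 and 1.09 at day 13. No p53 target, primitive streak or trophectoderm gene was at least 2-fold higher on both days. Medians were lower for the microRNA pathway (-0.24, percentile 2.80), stress (-0.93, percentile 0.16), fibroblast (-1.07, percentile 0.11) and fatty acid synthesis genes (-0.25, percentile 1.66). Of 10943 genes, 57 were at least 2-fold higher and 566 lower on both days, where independent days would share 1.3 and 65.2. With the day 13 median of all genes at -0.124, median scaling left 80 higher and 481 lower.

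Genes that fell with ΔSL1 also read lower with GW9662. Across 10943 genes the GW9662 log2 fold changes correlated with those of ΔSL1 embryoid bodies at 0.505 (day 10) and 0.492 (day 13), and genes are not independent. These 10943 genes had a value of at least 50 in 1 of the GW9662 or DMSO libraries. Of 1179 genes called at least 2-fold lower in ΔSL1, 706 were among the 10943. Those 706 had GW9662 medians of -1.12 and -1.23, against -0.22 and -0.29 for matched genes. On each day 91.6% of the 706 were lower, against 61.7% and 61.2% of all 10943 genes. Of 291 genes called at least 2-fold higher in ΔSL1, only 72 were among the 10943. Those 72 had medians of -0.11 and -0.23, at percentiles 92.9 and 61.5 of random lists, and the rest could not be compared. Afp was higher in ΔSL1 and lower with GW9662, though the DMSO libraries read it far above the WT libraries that were compared with ΔSL1.

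In neural differentiation of WT cells, most miR-290 members read lower and miR-10 and miR-219 members higher at day 5 than at day 0 (1 small RNA library each, no test). The posterior Hox-linked miR-10a-5p read 65105 against 87.8 (734-fold), miR-10b-5p 7282 against 55.5, the glial miR-219a-2-3p 1317 against 2.79, and the Hox-linked miR-196b-5p 911.7 against 17.4. The miR-99a-5p, which shares a family with miR-100, read 2160 against 0.822. The mESC miRNAs miR-290a-5p (171.7 against 4113), miR-291a-5p (536.3 against 11927), miR-293-5p (5244 against 57628) and miR-292a-5p (8952 against 90590) were lower. At day 5 miR-10a-5p held 11.8% of miRNA reads, miR-20a-5p 5.50% and miR-21a-5p 4.04%. The miR-290 cluster, counted without miR-290a, held 46.8% of miRNA reads at day 0 and still 10.5% at day 5. The Dlk1-Dio3 cluster held 4.58% and 18.3%.

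By list, the miR-290 cluster, counted without miR-290a, was at least 2-fold lower for 11 of 12 at day 5 (median -2.86). In contrast, 3 of 6 let-7 (0.99) and 3 of 5 Microprocessor-independent miRNAs (1.04) were higher. Dlk1-Dio3 miRNAs had 29 of 56 higher and 2 lower (1.13), Sfmbt2 miRNAs 3 of 13 higher and 1 lower (0.62), and neural miRNAs 5 of 11 higher (0.84) and 3 lower. Those 3 were miR-124-3p (54.0 against 355.3), miR-124-5p (29.7 against 76.1) and miR-128-3p (588.7 against 1190). The miR-302 cluster had 1 of 1 higher, the miR-200 family 1 of 6 lower (-0.53), other abundant miRNAs 10 of 36 higher and 6 lower (0.15), and tissue and lineage miRNAs 3 of 14 higher and 1 lower (0.01). The miR-17/92 and paralogous clusters had a median of -0.07 as deposited and 0.42 as a share of reads. Of 323 miRNAs 121 were at least 2-fold higher and 58 lower, a split that trimmed-mean scaling turned to 79 and 107 and shares of miRNA reads to 159 and 39.

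Human cell lines were sequenced for small RNA with 1 library per line, so shares of miRNA reads are given without a test. The oncogenic miR-21-5p ranked first in HepG2 (54.2%), HCT116 (52.6%), U2OS (47.3%), H1299 (41.4%) and K562 (21.8%). HEK-293T was led by miR-92a-3p of the miR-17/92 cluster (15.2%), with miR-20a-5p (8.17%) and the digestive-tract miRNA miR-148a-3p (7.33%) next. K562 also held miR-92a-3p (16.0%), miR-20a-5p (11.7%) and the immune-linked miR-146b-5p (6.87%). The miR-221-3p was second in U2OS (6.21%) and HCT116 (2.89%), miR-100-5p in H1299 (5.53%), and miR-148a-3p in HepG2 (3.62%). The let-7 family made up 8.05% in HCT116, 4.17% in U2OS, 3.09% in H1299, 2.62% in HEK-293T, 0.984% in HepG2 and 0.766% in K562. Summed values ran from 336799 in K562 to 1000000 in HCT116, a 2.97-fold range that follows from the deposited factors.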

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

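The tests of explanations in this part were chosen after the result was seen. The planned exception was the comparison of divisions of the embryoid body libraries, which was restricted to divisions within days afterwards.

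The lower miRNA total in ΔSL1 mESC ran against the higher Dgcr8 mRNA of the same cells. A loss limited to the 10 most abundant miRNAs would need their share of miRNA reads to drop by 25.5 percentage points, and it differed by 2.49 (standard error 2.24) in the other direction, which argues against it as the only cause. A loss of Microprocessor processing alone would spare Microprocessor-independent miRNAs, of which 4 of 5 fell as deposited. A single factor per library could account for most of the loss, but so could a true loss shared by all miRNAs. Scaling each library to its own miRNA total removes both by construction, so it cannot tell them apart. It left 1 of 168 calls and moved the median from -0.925 to -0.107. For the miR-200 family, whose log2 share of miRNA reads differed by -1.14 (standard error 0.28), 2 libraries per genotype are too few to tell whether a single factor per library is the whole cause.

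Embryoid bodies of ΔSL1 cells held more yolk sac and fewer neural transcripts. Of 17 yolk sac genes, 12 stood at least 2-fold above every WT day from 6 to 12 in the 1 ΔSL1 library of day 12. The mean log2 level of the list ran from 5.35 to 6.16 over the ΔSL1 days and from 3.01 to 4.4 in WT. These values argue against a delay of up to 6 days for yolk sac genes, while earlier WT days were not analysed here. The same delay could account for the neural genes, of which 21 of 23 lay between the lowest and the highest WT day, and stays open for them. The yolk sac median lay 2.20 above the highest of the blood (-0.26), cardiac (-0.33) and definitive endoderm (0.54) medians. This argues against a mere lack of neural cells, which would raise these lists alike. It does not exclude it, since the yolk sac rise was known when the comparison was chosen. Each day held 1 library per genotype, so only 8 of the 35 divisions of the 8 libraries exchange libraries within days alone, too few for a share under 0.05, and 1 of 8, the real one, reached 5318 calls, the highest other giving 0.

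Primary miRNA hairpin entries separated both mutants. Of 79 tested, 55 rose and 6 fell in DGCR8-/- mESC, and 0 of those 55 rose in ΔSL1. An upward scaling of the DGCR8-/- libraries cannot be the whole cause of this rise, because the hairpin median lay 1.79 above that of all genes. Such a scaling is not itself excluded, since the median of all genes stood at 0.279. In ΔSL1 1 hairpin rose and 6 fell, and the median log2 fold change of the 79 was -0.06 against 2.07 in DGCR8-/-. The ΔSL1 hairpin median thus lay below the median of all genes in that comparison, 0.28. Hairpin entries thus did not rise in ΔSL1 as they did in DGCR8-/-. The medians give no sign of a shared rise in ΔSL1. A weak loss of processing at single hairpins stays open, because calls from 2 libraries per group cannot exclude a small rise.

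Several genes moved in opposite directions in ΔSL1 and DGCR8-/- mESC, each at least 2-fold against WT, with limma and Benjamini-Hochberg adjusted p-values for the direct contrast. D7Ertd143e was higher in DGCR8-/- by 6.55 (-2.10 in ΔSL1, 4.45 in DGCR8-/-, limma adjusted p = 4.58e-13). Mir17hg, the host transcript of miR-17/92, was higher by 4.03 (-1.40 and 2.63, limma adjusted p = 1.17e-12). Wnt3a was higher by 3.41 (-1.42 and 1.99, limma adjusted p = 3.43e-08). Slc13a5 was lower by -4.57 (2.04 and -2.53, limma adjusted p = 1.37e-11). Dgcr8 itself was lower by -3.35 (1.51 and -1.84, limma adjusted p = 8.79e-13). Gata3 was also lower by -3.35 (1.68 and -1.67, limma adjusted p = 2.40e-09). Klf5 was lower by -2.35 (1.22 and -1.13, limma adjusted p = 3.20e-10).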

How the results depend on the processing

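The alternatives on recovered reads, the scaling of miRNAs to each library's own total and the pseudocount of 5 for single embryoid body days were chosen after the results were seen, and the others given here were planned. Requiring a 2-fold change left 2583, 6141 and 4586 genes in the ΔSL1, DGCR8-/- and direct mESC comparisons, with an overlap of 1551, then 2073, 2168 and 3552 in EpiLC at 6, 24 and 48 h and 1470 in embryoid bodies, which follows from the stricter rule. Leaving out 1 library or day at a time gave 3916 to 6247, 9018 to 10798 and 7331 to 9244 genes in mESC, 2495 to 4897, 3131 to 4376 and 4376 to 6820 in EpiLC, 2579 to 6865 in embryoid bodies, and 56 to 200 miRNAs. The cause was not tested.

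Without the day factor embryoid bodies gave 1178 genes, since the day then counts as spread. For miRNAs, median scaling gave 2, scaling to each library's own total 1, scaling to Microprocessor-independent miRNAs 25, edgeR with trimmed means 2 and DESeq2 15 against 168 as deposited, whereas edgeR with the deposited scaling gave 166. These alternatives remove the deposited factor by construction. On RNA-seq, edgeR gave 6105, 10371 and 9263 genes in mESC, 4526, 4611 and 6219 in EpiLC and 4579 in embryoid bodies, and DESeq2 5224, 9551 and 8323, 3910, 3947 and 5441, and 4862.

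Of 23 list calls at the preset correlation (16 up, 7 down), 2 were left with an estimated correlation, naive and formative genes at 48 h of EpiLC induction. Doubling the level left 333 genes in neural culture, an additive fit of day and GW9662 called 4089, a pseudocount of 5 left 128 genes on all embryoid body days, and median-ratio scaling gave the human totals a range of 2.18-fold. The cause was not tested.

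A replicate block over equal library numbers, which the labels do not state to be shared cultures, gave 6302 genes for ΔSL1 mESC, 6519, 6699 and 8195 in EpiLC and 142 miRNAs. Deviations of equally numbered libraries correlated at 0.365 to 0.5 in EpiLC, at -0.074 to -0.099 in mESC and at 0.082 for miRNAs. Of 10533 values of named genes under alternatives 9614 were the same, 817 weaker, 4 stronger, 98 moved and 0 reversed. Sets of genes with seed matches were not run.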

Other observations

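The counts of hairpin entries and the comparison of list medians between ΔSL1 and GW9662 were chosen after the results were seen, whereas the lists and the scaling to Microprocessor-independent miRNAs were planned. The imprinted transcript H19 showed how 1 library can decide a mean: it stood at 311.6 ± 391 in ΔSL1 mESC and was lower in DGCR8-/- by a log2 fold change of -3.78 with a standard error of 0.71. Hairpin entries had a median log2 fold change of 2.07 in DGCR8-/- and -0.06 in ΔSL1 mESC, where all genes had medians of 0.279 and 0.28. Afp moved in opposite directions in ΔSL1 and GW9662 embryoid bodies, but its control levels differed. The DMSO libraries read Afp far above the WT libraries that were compared with ΔSL1, so both comparisons start from unlike levels. Yolk sac genes rose with ΔSL1 (list median 2.74, 17 members) and read lower with GW9662 (-1.86, 8 members). Neural genes were lower in both (-1.68 with 23 members and -2.19 with 19).

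A hypothesis that ΔSL1 cells process primary miRNAs at least as well as WT could be tested with spike-in RNA. Scaling to Microprocessor-independent miRNAs gave 25 rises in place of 167 falls, but it cannot decide the question. That list fell more (median -1.73) than all miRNAs (-0.925), so dividing by it raises the others by construction. The log2 ratio of all other miRNAs to the list differed by only 0.85 (standard error 0.49) between ΔSL1 and WT.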
